A study of Drosophila melanogaster with 64 samples.

How the data were processed

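RNA was measured in 64 libraries of dissected Drosophila melanogaster testes. Males came from 8 lines: an irradiated parental stock that served as the control, and 7 lines carrying reciprocal translocations between the X and chromosome 2, T(1;2). Per the labels, 5 translocations were male-sterile (BM1, BM5, BM6, BM24 and BM46) and 2 were fertile (BM4 and BM21). Each line was sampled as adults and as larvae late in the third instar (L3), with 4 replicate pools per line and stage. Adult pools held 20 testes, from which the seminal vesicle had been separated, and L3 pools held 15 testes freed of fat body by an enzyme digest, per the labels' protocols. Sterile translocations were carried over females with the FM7i balancer, whereas fertile translocations and the parental stock were kept with compound-X C(1)M4 females. Sterility class and stock maintenance were therefore the same split of the lines.

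Per the labels' protocols, poly(A) RNA libraries that keep strand information were made from 350 ng of total RNA with ERCC spike-ins, and read as 50 bp single ends on an Illumina HiSeq with 8 libraries per lane. Samples were collected on different days, while extraction and library preparation were done together in a 96-well plate, per the same protocols. Which lane or day each sample had is not given in the sources used here. Per the submitters' processing notes, bcl2fastq 1.8, cutadapt (version not given in the sources used here), HISAT2 2.1.0 and featureCounts 1.6.1 were used. The deposited values are the authors' raw counts of reads per gene, not normalized. The genome build and the strand setting of the counting are not given in the sources used here. The count table lists 17606 genes, of which 17527 had an identifier in the Ensembl BDGP6 annotation, and 17494 of these had the same chromosome, start and end there. Coordinates are those of the count table. Without the strand setting, counts of antisense genes, overlapping genes and members of families with near-identical copies (Pp1-Y, Lsp1, Mst84D and Stellate genes) are uncertain. Spike-in counts were not used here.

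Total counts ran from 20387 to 24650332 in adult libraries and from 8961413 to 21275143 in L3 libraries. Adult BM6 replicate 3 (20387 counts), BM24 replicate 3 (43347) and BM24 replicate 2 (233047) lay under 1000000; all 3 entered the tests, and the adult counts of called genes, class lists and arm levels were computed again without them. No library repeated another: none of the 96 pairs of libraries within a group had identical columns, and in the 88 pairs without a shallow library the chi-square per degree of freedom over genes was 2.53 to 64.5. The labels call the replicates pools and do not say whether they came from separate crosses. The p-values of the line and stage tests therefore measure the spread between these pools, which may be technical.

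Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05, log2 fold changes with standard errors), and files were read with the R package data.table (version 1.17.8). For sterile against fertile lines the 4 libraries of a line were summed, so that the line was the replicate (5 lines against 3, per stage). The interaction of stage and sterility used the 16 sums, with the line as a block. Each translocation was compared with the parental stock in a fit of all 32 libraries of the stage, and adult with L3 parental testes in a fit of their 8 libraries. Adjusted p-values given for genes without naming another tool are edgeR's. All these designs, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined.

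There were 22 gene lists: spermatogonial genes, testis-specific TAF and tMAC regulators, meiotic genes, spermatocyte-transcribed differentiation genes, postmeiotic cup and comet genes, sperm nuclear proteins, sperm leucylaminopeptidases, testis-specific proteasome subunits, Y-linked fertility genes, Stellate genes, the piRNA pathway, the dosage compensation complex, somatic cyst and hub genes, muscle, fat body, accessory gland and duct, and hemocyte genes, antimicrobial peptides, heat shock proteins, DNA damage and apoptosis genes, ribosomal proteins and ubiquitous proteasome subunits. Each list with at least 3 tested genes was tested with limma 3.58.1 camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. For an arm, the level in a library was the mean log2 CPM of its tested genes minus that of chromosome 3 genes, with a prior count of 2. These levels were compared by exact two-sided permutation tests.

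Genes were named by a fixed rule. In the class and stage comparisons it took genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups' lines (libraries for stage), and among them the 10 largest changes each way. For the interaction it took the 5 largest each way, and for each translocation the 2 largest each way with its 4 libraries beyond all 4 parental ones. From each list it took up to 4 members with the smallest unadjusted p. Other named genes were chosen after their values were seen and are marked so. A fold against a group at 0 counts is a lower bound set by a floor of 3 counts over the group, and a ratio to 1 to 3 counts carries its 95% counting interval. Floors and intervals cover counting error only.

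The tests were checked on simulated counts drawn from the real means and library sizes, with 200 changed genes per run. The changed genes were taken only from those above a set mean expression, so recovery of scarce transcripts was not tested. For 2-fold changes 64% were recovered in the adult class test (97% for 4-fold; 9 false calls; 13453 genes) and 90% in the L3 class test (100%; 10; 13023 genes). For the interaction the shares were 82% and 99% (8; 13849 genes), and for stage 99% and 100% (10; 11170 genes). Adult BM1 gave 97% and 100% (9; 12512 genes), and adult BM24, with its shallow libraries, 88% and 99% (11; 12519 genes). The L3 tests of BM1 (11924 genes) and BM24 (11921 genes) recovered 100% at both fold sizes with 8 false calls each. In a simulation of the L3 lists, camera called the 1 shifted list and 0 of the others among 21. The simulated genes were drawn independently of each other. That run therefore cannot show whether the preset correlation suits the real lists. The step finder used for the X, run on 2000 simulated genes, placed a planted step within a median of 9.5 genes.

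Alternatives covered DESeq2 1.42.0, limma voom with the line as a random effect, other scalings, no low-count filter, fits of single libraries, the plate row read from the column names as a covariate, a replicate block, and leaving out each line or replicate. Chosen after seeing the data were the runs without the 3 shallow libraries, the runs without adult libraries above a mean log2 CPM of 3 over the accessory gland list, the lists with each line left out, and the unfiltered and median forms of the arm levels per line.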

Results

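Poly(A) RNA of dissected testes was counted in 64 libraries, from 8 Drosophila lines at 2 stages with 4 pools each. Adult depth ranged over lines from 15865499 to 17769116 counts per library in BM1, 9786466 to 14308506 in BM5, 20387 to 23942015 in BM6, 43347 to 18517329 in BM24 and 12490971 to 15062874 in BM46. In the fertile lines it was 11546705 to 22700672 in BM4, 13919845 to 21328397 in BM21 and 2971832 to 24650332 in the parental stock. L3 depth was more even, with 11299602 to 15111991 in BM1, 12335310 to 20447998 in BM5, 17297707 to 21275143 in BM6, 12077672 to 19054887 in BM24 and 12946732 to 18869462 in BM46. The fertile lines had 9644557 to 16785351 in BM4, 10458575 to 18575476 in BM21 and 8961413 to 14845562 in the parental stock. In adult testes, transcripts of the accessory gland, which makes seminal fluid proteins and lies next to the dissected tissue, were unevenly present. Their list of 23 genes had a mean log2 CPM above 3 in 7 libraries (BM1 replicates 1 and 4, BM4 replicates 2 and 3, BM6 replicates 1 and 2, and BM21 replicate 4). Their values were 4.02 to 6.77, and those of the other adult libraries at most 1.90. This limit was chosen after the values were seen, and 4 of the 7 libraries were from sterile lines.

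The parental stock shows what differs between the stages without a translocation. Adult testes held more RNA of genes used late in sperm formation, and L3 testes more of the genes that start the spermatocyte programme. All 18 spermatocyte-transcribed differentiation genes rose in adults, among them Mst98Ca (2714 ± 188 CPM in adults against 1058 ± 123 in L3, SD, n = 4 each, log2 change 1.39 ± 0.10 SE) and the sperm tail gene dj (1.36 ± 0.09). So did 16 of 17 cup and comet genes, which are transcribed after meiosis, such as w-cup (2.06 ± 0.08), while 1 fell. Also higher were 10 of 12 sperm nuclear protein genes, including Mst77F, which packs sperm DNA (0.52), all 8 sperm leucylaminopeptidases, and 10 of 11 Y-linked fertility genes, with the dynein heavy chain gene kl-3 at 1.67 ± 0.12. In the other direction, 13 of 14 TAF and tMAC regulators fell, including aly, which opens the meiotic programme (51.8 ± 5.26 against 95.8 ± 3.95 CPM, a change of −0.87 ± 0.08). So did 11 of 14 spermatogonial genes such as bam, the switch from mitotic divisions to differentiation (−0.77 ± 0.10), and 22 of 26 piRNA pathway genes such as aub (−0.79 ± 0.11). Ribosomal protein genes fell in 52 of 55 cases and ubiquitous proteasome genes in 26 of 31.

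In all, 4069 of 11286 tested genes rose and 4350 fell from L3 to adult parental testes (edgeR adjusted p under 0.05, with 8606 at an unadjusted p under 0.05). Scaling by library size alone lowered the median of all genes from −0.05 to −0.47, a shift of −0.41, and with it the share of higher genes among those called from 48.3% to 29.6%. The largest rises were in CG10513 (3R 25275790 to 25277212; 0 L3 counts, at least 798-fold), CG18628 (3L 10639740 to 10640136; 12.16 ± 0.27, adjusted p = 1.85e-12) and CG12506 (2L 773547 to 774017; 11.24 ± 0.23). CG18628 went from 0.839 ± 0.558 to 3460 ± 674 CPM. CG3713, CG42870, CG12645 and CG43207 also had 0 L3 counts and were at least 616, 538, 274 and 265-fold higher. Ratios to 1 or 2 L3 counts were 5465 (980 to 2.16e+05) for CG32457, 2248 (403 to 88835) for the amino acid transporter gene NAAT1 and 1646 (455 to 13600) for CG16772. The Notch targets E(spl)mbeta-HLH (−6.30 ± 0.33) and E(spl)m2-BFM (−6.26 ± 0.26) fell most, and E(spl)malpha-BFM had 1 adult count (ratio 297, 52.8 to 11760). Also lower were the ecdysone response gene br (7.06 ± 1.49 against 45.4 ± 4.0 CPM, −2.73 ± 0.14), the larval serum protein genes Lsp1gamma, Lsp1alpha and Lsp1beta (−2.97, −2.95 and −2.58), Cpr49Ac, ltl and CG41562.

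Among the stage lists, markers of muscle, hemocytes and the accessory gland moved as well. Muscle genes mark the sheath around the testis as well as any surrounding muscle, so they are not markers of other tissue only. Of 19 muscle genes 17 rose, Mhc (27.6 ± 8.04 against 1.15 ± 0.392 CPM, 4.60 ± 0.25) and Act57B (5.25 ± 0.35) among them, with 8 of 9 hemocyte genes and 5 of 6 accessory gland genes. Camera (limma) gave an adjusted p of 1.33e-06 for muscle, 8.38e-08 for ribosomal proteins, 2.67e-05 for the TAF and tMAC list and for the cup and comet list. It gave 3.14e-05 for differentiation genes, 7.17e-05 for the ubiquitous proteasome and 4.88e-04 for piRNA genes. It gave 0.00323 for sperm nuclear proteins, 0.00511 for spermatogonial genes, 0.00757 for leucylaminopeptidases, 0.0142 for hemocytes, 0.0195 for Y-linked genes, 0.0308 for accessory gland and 0.0479 for cyst and hub genes. The cyst and hub list (13 higher and 6 lower of 24) had a median of 0.35 that turned to −0.05 when scaled by library size alone. None of these list calls held with an estimated correlation. Limma's adjusted p was 0.184 with an estimated correlation for the spermatogonial and the TAF and tMAC lists, 0.188 for muscle and the ubiquitous proteasome, 0.223 for accessory gland, and 0.231 for cup and comet genes. It was 0.285 for piRNA, ribosomal and cyst and hub genes, 0.315 for nuclear proteins and hemocytes, 0.336 for differentiation, 0.429 for leucylaminopeptidases and 0.452 for Y-linked genes. Lists that did not pass were meiotic genes (adjusted p = 0.237, limma), testis-specific proteasome (0.515), dosage compensation (0.0650), fat body (0.485), antimicrobial peptides (0.448), heat shock (0.501) and DNA damage genes (0.485). Heat shock genes had a median of −0.10 and a mean of 0.15, and DNA damage genes −0.13 and 0.28, both tested as lower. Counts adjusted over the list alone were 18 of 19 for muscle, 20 of 24 for cyst and hub, 17 of 17 for cup and comet, 52 of 55 for ribosomal proteins and 23 of 26 for piRNA genes.

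The comparison of 5 sterile with 3 fertile lines asked which transcripts go with male sterility of the translocations. In adult testes, 201 genes rose and 174 fell in sterile lines among 13596 tested (edgeR, with 3029 at an unadjusted p under 0.05). lncRNA:CR43453 (FBgn0263407, 3R 21465701 to 21466492) reached 33.3 ± 17.8 CPM (SD, n = 5 lines) with 3 counts in all fertile libraries together, a ratio of 2125 (727 to 10306). CG14369 (FBgn0038159, 3R 13591632 to 13592657) reached 12.5 ± 7.56 CPM with 3 counts (ratio 804, 275 to 3899). CG9616 (FBgn0038214, 3R 14244804 to 14245471) rose from 0.149 ± 0.0492 to 13.3 ± 5.88 CPM (6.48 ± 0.55, adjusted p = 0.00166), and lncRNA:CR43451 (8.82 ± 0.91) and lncRNA:CR43882 (5.92 ± 0.44) rose likewise. The other leading rises were lncRNA:CR46088, lncRNA:CR44547, CG43445, lncRNA:CR44941 and lncRNA:CR44735, at 4.91 to 7.55.

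Lower in adult sterile lines were asRNA:CR46044 (FBgn0267711, 3R 20588003 to 20588549), at 0.256 ± 0.0694 against 8.52 ± 1.14 CPM (−5.06 ± 0.26, adjusted p = 0.000147), and lncRNA:CR44138 (−4.73). The antisense position of asRNA:CR46044 leaves its counts uncertain. CG2772 (2L 3445992 to 3447589) fell (−3.99 ± 0.33), and CG43707 (2L 3757256 to 3769525) went from 12.3 ± 1.06 to 1.25 ± 0.281 CPM (−3.28 ± 0.20). CG42828, CG15563, GILT3, sprt, lncRNA:CR44080 and CG5639 fell by 2.38 to 3.51 on the log2 scale. The share of higher genes was 53.6%, and 36.3% when scaled by library size alone. Without BM4 the count was 110, without BM21 144, without BM6 177, without BM5 186, without the parental stock 191, without BM46 205 and without BM1 217. With the plate row as a covariate it was 34, and there lncRNA:CR43453 had an adjusted p of 0.0575. The adult parental stock and BM46 were each alone in their plate row, so that fit drew its class difference from the other lines only.

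Muscle genes, which mark the sheath around the testis and any surrounding muscle in the pool, were the clearest list in adult sterile lines. Of 22 tested, bt (0.56 ± 0.12, adjusted p = 0.0445) passed over all genes and 13 when adjusted over the list alone. The median was 0.64 (limma adjusted p = 9.42e-06, and adjusted p = 0.576 with an estimated correlation). Mlp60A (1.22, adjusted p = 0.0503), Mhc (0.85, 0.0521) and Mp20 (1.13, 0.0550) lay just beyond the threshold. The piRNA list, which silences transposons in the germline, was lower with a median of −0.25 over 27 genes (adjusted p = 0.00423, limma), although 0 single members passed, and 0 when adjusted over the list alone. TAF and tMAC regulators (median −0.28), differentiation genes (0.15), leucylaminopeptidases (0.18) and fat body genes (0.61) each had an adjusted p of 0.0495 (limma), with 0, 0, 0 and 1 members called adjusted over the list alone. All 5 lists had an adjusted p = 0.576 with an estimated correlation. The fat body member was Apoltp, a lipid transfer apolipoprotein, at 54.2 ± 8.86 CPM in sterile and 10.4 ± 1.36 in fertile lines (2.38 ± 0.17, adjusted p = 0.000792). At the preset correlation, muscle and piRNA lists passed with each line left out in turn, the highest adjusted p being 1.67e-04 and 0.0283 (limma). The others were lost in most of these runs, with an adjusted p of up to 0.148 for TAF and tMAC, 0.207 for differentiation, 0.231 for leucylaminopeptidases and 0.134 for fat body genes, all without BM4. The adult fat body list was uneven between libraries and lines. Its mean log2 CPM was 5.47 in BM46 replicate 1 and 2.48 to 2.71 in the other BM46 libraries, and 4.33 and 2.13 in the deep BM24 libraries. Line means without shallow libraries were 2.25 (BM6) to 3.33 (BM46) in sterile and 2.52 (BM4) to 2.99 (parental stock) in fertile lines, so sterile BM6 was the lowest of all.

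The remaining adult lists did not pass between the classes. Among germline lists limma's adjusted p was 0.117 for meiotic and for spermatogonial genes, 0.824 for cup and comet genes and for the testis-specific proteasome, 0.137 for sperm nuclear proteins, 0.130 for Y-linked genes and 0.154 for dosage compensation. For other tissues it was 0.366 for cyst and hub, 0.571 for accessory gland and 0.10 for hemocyte genes. It was 0.862 for antimicrobial peptides, 0.909 for heat shock, 0.108 for DNA damage, 0.10 for ribosomal and 0.130 for ubiquitous proteasome genes. Adjusted over the list alone, 5 of 20 DNA damage, 4 of 14 spermatogonial, 2 of 12 meiotic, 1 of 8 dosage compensation, 1 of 14 testis-specific and 1 of 31 ubiquitous proteasome genes were called, and 0 in the others. The cup and comet median was 0.03, or −0.05 when scaled by library size alone. Median and mean differed in sign for the testis-specific proteasome (0.08 and −0.01) and the ubiquitous one (−0.03 and 0.04, tested as lower). Within them, Prosbeta4R2, a testis-specific proteasome subunit, fell (56.1 ± 2.21 against 130 ± 17.96 CPM, −1.20 ± 0.09, adjusted p = 0.00117), as did Rpt5 (−0.52 ± 0.10, 0.0408), and the pro-apoptotic gene hid rose (0.91 ± 0.19, 0.0453). Without BM4 the adjusted p was 0.165 for Rpt5, 0.151 for hid and 0.175 for bt. The Stellate list had fewer than 3 tested genes. Ste12DOR was at −0.46 (adjusted p = 0.629) in adults and −1.53 (0.155) in L3, with reads uncertain among its near-identical copies. Accessory gland transcripts differed in median by 1.36 without passing, and without the 7 libraries that held most of them the muscle list kept an adjusted p of 3.62e-05 (limma) and the piRNA list 0.00743, and the hemocyte list passed as higher (0.0477). These are values at the preset correlation, and with an estimated one, tested on all libraries, all 3 lists had an adjusted p = 0.576 (limma).

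In L3 testes 428 genes rose and 298 fell in sterile lines among 13132 tested (edgeR, with 2847 at an unadjusted p under 0.05). Fat body genes formed the clearest group, in which 9 of 17 rose and 0 fell. They included the larval serum protein genes Lsp1alpha (2.70 ± 0.30, adjusted p = 0.00119), Lsp1beta (2.55 ± 0.34), Lsp1gamma (2.41) and Lsp2 (1.74), and the fat body protein genes Fbp1 (2.47) and Fbp2 (2.32 ± 0.23). Apoltp rose from 4.39 ± 1.08 to 29.5 ± 8.48 CPM (2.74 ± 0.26), and CG2233 (1.89) and the lipoprotein gene apolpp (1.03) rose too. The median of the list was 1.74, with 12 called when adjusted over the list alone (limma adjusted p = 3.95e-07, and adjusted p = 0.284 with an estimated correlation), and it passed with each line left out, at 3.75e-08 to 3.85e-05. The Lsp1 genes resemble each other, so reads could be split among them, and Lsp1alpha lost its call with limma voom (adjusted p = 0.0768).

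**Figure D1:**
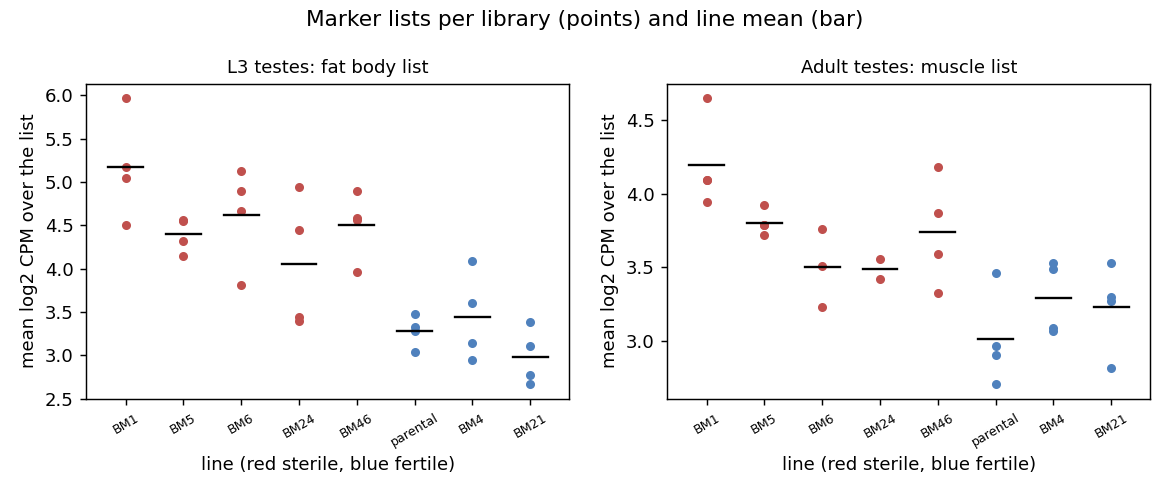
Mean log2 CPM of the fat body list in L3 testes and of the muscle list in adult testes, per library (points; red sterile, blue fertile and parental lines) and per line (bars, the mean). The 3 adult libraries under 1000000 counts are not drawn; L3 fat body means run from 4.06 to 5.17 in the 5 sterile lines and from 2.98 to 3.44 in the other 3, and adult muscle means from 3.49 to 4.20 and from 3.01 to 3.29.

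The leading L3 rises again included lncRNA:CR43453 (4.18 ± 1.89 CPM against 2 counts in all fertile libraries, a ratio of 350, 96.6 to 2889), CG14369 (11.98 ± 3.88 against 0.0506 CPM, 7.90 ± 0.59, adjusted p = 0.000235) and CG9616 (6.28 ± 0.59). TwdlD (FBgn0039444, 3R 26640025 to 26641054), a cuticle protein gene, rose by 5.76 ± 0.61. The mechanosensory channel gene nompC (FBgn0016920, 2L 5346200 to 5365760) rose by 4.83 ± 0.40 (5.98 ± 2.32 against 0.208 ± 0.0705 CPM), and the juvenile hormone inducible gene JhI-26 (FBgn0028424, 2R 16289320 to 16291333) by 3.69 ± 0.42 (29.5 ± 8.05 against 2.28 ± 1.52 CPM). lncRNA:CR45982, lncRNA:CR46088, lncRNA:CR44903 and lncRNA:CR43451 rose by 3.91 to 5.0 on the log2 scale. asRNA:CR43464 (2L 2000058 to 2003935), with counts uncertain as for other antisense genes, and CG43291 (3R 14234984 to 14244677), the neighbour of CG9616, fell most (−5.35 ± 0.54 and −5.04 ± 0.59). The pseudogene CR43142 (2L 6972243 to 6972796) fell from 22.1 ± 2.59 to 3.18 ± 0.596 CPM (−2.80 ± 0.16, adjusted p = 9.09e-05). nAChRbeta1 (3L 4429349 to 4435993), a nicotinic receptor subunit gene, fell from 9.45 ± 4.30 to 2.36 ± 0.768 CPM (−2.01 ± 0.32). lncRNA:CR44080, CG31777, ND-AGGG, CG15563, lncRNA:CR45438 and CG43707 fell by 1.98 to 3.12. Without BM1 the count was 404, without BM6 418 and without BM4 428, and with the plate row as a covariate 238. In that last fit sterile BM24 and BM46 shared a row without a fertile line, so they did not enter the class difference.

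Y-linked fertility genes (median 0.42), accessory gland genes (0.35) and hemocyte genes (0.23) were higher in L3 sterile lines, each list with an adjusted p of 0.0365 (limma). Adjusted over the list alone, 3 of 12, 0 of 8 and 5 of 11 were called. Over all genes, CCY (0.69 ± 0.17) was called among the Y-linked genes, and NimC4 (1.88), NimC2 (1.85) and the collagen gene Col4a1 (0.68) among the hemocyte genes. With an estimated correlation the adjusted p was 0.898 for Y-linked and hemocyte genes and 0.308 for accessory gland genes. Each of these lists was lost in 3 of 8 runs with a line left out, with the highest adjusted p at 0.432 without BM4, 0.286 without BM4 and 0.268 without the parental stock, respectively (limma). SA2, which pairs homologues in male meiosis, fell (41.6 ± 4.89 against 67.0 ± 10.6 CPM, −0.69 ± 0.12, adjusted p = 0.0102). Single members of other lists passed as well, namely the TAF and tMAC regulators vis (−0.33) and tomb (−0.36), Rbfox1 (0.43), wb (0.70 ± 0.12), sls (0.41 ± 0.08), the antifungal peptide gene Drs (2.58 ± 0.58) and the checkpoint kinase gene lok (−0.48). Of these, wb passed with every line left out. Without BM4 the adjusted p was 0.0515 for NimC4, 0.132 for Col4a1, 0.133 for CCY, 0.135 for tomb, 0.109 for Drs, 0.106 for lok and 0.0642 for sls. Without BM21 it was 0.111 for NimC2 and 0.0732 for Rbfox1, and without the parental stock 0.0977 for vis.

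The other L3 lists did not pass. Among germline lists limma's adjusted p was 0.872 for spermatogonial genes, 0.165 for TAF and tMAC regulators, and 0.589 for meiotic genes, differentiation genes, nuclear proteins and the testis-specific proteasome. It was 0.572 for cup and comet genes, 0.363 for leucylaminopeptidases, 0.507 for piRNA genes and 0.428 for dosage compensation. For the rest it was 0.292 for cyst and hub, 0.572 for muscle, 0.851 for antimicrobial, 0.696 for heat shock, 0.807 for DNA damage, 0.363 for ribosomal and 0.179 for ubiquitous proteasome genes. Adjusted over the list alone, 4 of 14 TAF and tMAC, 2 of 14 testis-specific proteasome, 2 of 17 muscle, 1 of 14 spermatogonial, 1 of 12 meiotic, 1 of 24 cyst and hub, 1 of 8 antimicrobial and 1 of 19 DNA damage genes were called, and 0 in the others. Spermatogonial genes had a median of −0.0041 against a test in the upward direction (0.0017 with DESeq2 size factors), and heat shock genes −0.0013 (0.0043 with DESeq2 size factors). Median and mean differed in sign for muscle (−0.03 and 0.07, tested as higher), antimicrobial (−0.05 and 0.17, tested as higher) and DNA damage genes (−0.04 and 0.03, tested as lower).

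Between stages the class differences ran in parallel. Among 12825 genes tested at both stages, 195 were called in both, 116 higher and 79 lower in sterile lines each time, where independent lists would share 6.58 and 3.83. Adult and L3 values came from different libraries of the same 8 lines, so inherited differences between the lines enter both. Of 369 adult calls 366 had the same sign in L3, and the log2 changes correlated across genes (r = 0.736, rho = 0.656), which are not independent replicates. The test for a class difference that depends on stage called 0 of 13994 genes in edgeR, with 1509 at an unadjusted p under 0.05, and DESeq2 called 190. The smallest adjusted p was 0.0551, shared by genes chosen after their values were seen: nahoda (1.31), the cuticle gene Cpr92A (3.22), the DNA polymerase gene PolE1 (−1.02) and Spn28Dc (−1.74). The count was 8 without the 7 adult libraries rich in accessory gland transcripts, 8 without a low-count filter, 9 with DESeq2 size factors, and 4 without BM5 and 4 without BM21.

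Called genes were unevenly spread over the arms. On the X, 6 of 2079 tested genes differed between the classes in adults (1 higher, 5 lower), 0.289% against 3.20% elsewhere (odds ratio 0.0874, 95% interval 0.0318 to 0.193; Fisher's exact test, two-sided, p = 9.59e-20). In L3 it was 27 of 2034 (20 higher, 7 lower), 1.33% against 6.30% (0.200, 0.131 to 0.295; exact p = 2.48e-25). Arm 2L held more than its share at both stages, with 118 of 2658 genes in adults (odds ratio 1.93, 1.53 to 2.42; exact p = 3.12e-08) and 201 of 2541 in L3 (1.65, 1.38 to 1.95; exact p = 2.32e-08). In L3, 3R was also above its share (207 of 3203, 1.25, 1.06 to 1.48; exact p = 0.00869) and 2R below it (120 of 2582, 0.800, 0.649 to 0.980; exact p = 0.0305). The other arms had exact p-values of 0.0773 to 1.00 in adults and 0.0813 to 0.821 in L3. Among the calls of single lines against the parental stock, X genes were scarce in fertile BM4, at 8.88% against 19.4% elsewhere in adults (odds ratio 0.404, 0.341 to 0.475; exact p = 3.01e-33) and 24.5% against 40.1% in L3 (0.485; exact p = 2.03e-39). In BM21 the odds ratio was 0.646 in adults (exact p = 4.14e-11) and 0.626 in L3 (exact p = 1.33e-17). In sterile BM1, BM5, BM6 and BM24 it was 0.771 to 0.906 in adults (exact p up to 0.0520, in BM6) and 0.601 to 0.858 in L3 (exact p up to 0.00286), and in BM46 it was 1.05 (exact p = 0.351) and 1.00 (exact p = 1.00). Genes are not independent replicates, so these p-values describe the lists.

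Each translocation line was next compared with the parental stock, in adult testes first. The same 4 parental libraries enter all 7 comparisons, so values shared by lines rest partly on them. CG44355 (FBgn0265455, 3L 12310805 to 12311961) had 0 counts in the adult parental libraries and was at least 512-fold higher in BM1, 604 in BM5, 917 in BM6, 834 in BM24, 919 in BM46, 565 in BM4 and 628 in BM21. CG13675 (FBgn0035845), at 105 ± 10.6 CPM in adult parental testes, was nearly lost in 5 lines. It had 2 counts in BM1 (ratio 3283, 908 to 27115) and 1 count in BM46 (5490, 985 to 2.17e+05), and changed by −10.08 ± 0.39 in BM5, −9.98 ± 0.42 in BM6 and −9.92 ± 0.37 in BM4. Other genes at 0 parental counts were lncRNA:CR46414 (at least 167-fold in BM24, 406 in BM4 and 247 in BM21), lncRNA:CR46088 (434, BM1), CG14369 (219, BM5) and lncRNA:CR46215 (196, BM6). lncRNA:CR43453 had 1 parental count (ratio 3260 in BM46, 585 to 1.29e+05). At 0 in a line were lncRNA:CR43846 (at least 267-fold lower in BM1, 223 in BM46), lncRNA:CR43399 (171 in BM5, 194 in BM6; 1 count in BM4, ratio 721, 129 to 28529) and Muc30E (117, BM24). CG42714 had 1 count in BM24 (ratio 372, 66.6 to 14732), and lncRNA:CR46212 (−4.88) and the cytochrome P450 gene Cyp6a14 (−4.33 ± 0.29) led the falls in BM21.

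Of 12713 adult genes tested, 3401 rose and 3106 fell in BM1, 1985 and 1964 in BM5, 2516 and 2378 in BM6, 1902 and 1720 in BM24, 2164 and 2162 in BM46, 1160 and 1105 in BM4, and 1400 and 1095 in BM21 (edgeR). Totals averaged 4660 ± 1136 in the 5 sterile lines and 2380 in the 2 fertile ones (exact permutation test, two-sided, p = 0.0952; the smallest possible is 0.0476). Without the 3 shallow libraries the counts were 7775 in BM1, 5264 in BM5, 6325 in BM6, 4768 in BM24 and 5688 in BM46, against 3487 in BM4 and 3788 in BM21. Without the 7 libraries rich in accessory gland transcripts they were 4847, 4146, 2807, 3710 and 4455 in the sterile lines in that order, against 1696 in BM4 and 2390 in BM21. BM1, BM4 and BM6 then kept 2 libraries each, and replicate 3 of BM6 held only 20387 counts, so fewer data enter these counts. DESeq2 called 4090 genes in BM1, 2072 in BM5, 2696 in BM6, 1887 in BM24, 2267 in BM46, 1154 in BM4 and 1182 in BM21. The share of higher genes moved by scaling from 52.3% to 39.6% in BM1, from 50.3% to 36.9% in BM5 and from 51.2% to 62.1% in BM4 when only library size was used, which in BM1 shifted the median of all genes from 0.03 to −0.09, by −0.12. Falls then also outnumbered rises in BM6 (2898 and 2323) and BM46 (2681 and 1914). With DESeq2 size factors they did so in BM5 (2141 and 1940), BM6 (2545 and 2476) and BM46 (2296 and 2133), so the prevailing direction over all called genes in these lines is not settled. Among called genes that changed at least 2-fold under TMM, rises outnumbered falls in BM5 (856 and 430), BM6 (1253 and 453) and BM46 (810 and 395). The 2-fold counts were not repeated under the other scalings.

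**Figure D2:**
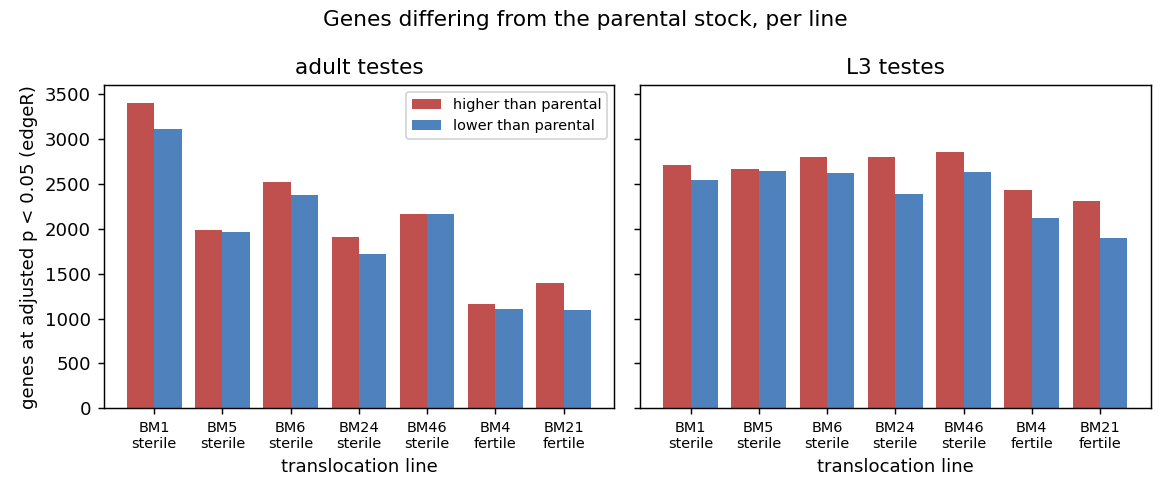
Number of genes called higher (red) or lower (blue) than the parental stock in each translocation line, in adult and L3 testes (edgeR adjusted p under 0.05; 4 libraries per line). Sterile lines stand left of the fertile BM4 and BM21; adult totals of higher genes run from 1160 in BM4 to 3401 in BM1, and L3 totals from 2313 in BM21 to 2855 in BM46.

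By list, muscle genes rose in adult BM1 (18 of 22, median 1.37), BM5 (12 higher, 1 lower, median 0.80) and BM46 (15 higher, 1 lower, median 0.76). In BM1 these included Act57B (1.71 ± 0.30) and Mhc (1.13 ± 0.24). Limma's adjusted p was 3.16e-04, 0.0430 and 0.0168, and 0.874, 0.988 and 0.919 with an estimated correlation. Adjusted over the list alone, 18, 15 and 18 genes were called. In BM6, BM24, BM4 and BM21 the list did not pass, with 7, 5, 2 and 1 members higher. Accessory gland genes, such as the seminal protein gene Acp26Aa (7.31 ± 1.8 in BM1), rose in BM1 (21 of 23), BM6 (16) and BM4 (2). Limma's adjusted p was 1.77e-07, 4.16e-04 and 3.70e-05, with an adjusted p = 0.874, 0.946 and 1.00 with an estimated correlation. These are lines with libraries rich in these transcripts. Without the 7 rich libraries 3 of 19, 0 and 0 members were higher in BM1, BM6 and BM4. In BM21, which lost 1 library, 7 of 19 were higher (median 1.37), and in lines without a rich library 5 in BM5, 3 in BM46 and 0 in BM24, where 1 was lower. Without these libraries 17 of 22 muscle genes were higher in BM1 (median 1.19), 14 in BM5, 16 in BM46 and 6 in BM24 (1 lower in each of these 3). In BM6 the 7 higher muscle genes became 1, with 1 lower (median 0.50 before and 0.22 after), and BM4 and BM21 had 1 and 2 higher. BM6 kept 2 libraries in these runs, of which replicate 3 held only 20387 counts. Its lost muscle and accessory gland calls may therefore reflect lost data, which was not tested. BM1 was also lower for meiotic (8 of 12, 1 higher) and piRNA genes (16 of 27, 2 higher) and higher for differentiation genes (8 of 18). Limma's adjusted p was 0.0212, 0.0362 and 0.00680, all with an adjusted p = 0.874 with an estimated correlation. Without the rich libraries, which left 2 of BM1, 6 of 12 meiotic genes were lower (1 higher) and 10 of 27 piRNA genes (2 higher). Of the differentiation genes 7 of 18 were then higher. Ribosomal protein genes fell in BM6 (30 of 55, median −0.38, adjusted p = 1.96e-07, limma, and adjusted p = 0.946 with an estimated correlation), where 7 of 11 Y-linked genes were higher without a list call. Fat body genes tested as higher in BM24 (8 higher, 1 lower of 15, adjusted p = 8.47e-04, limma, and adjusted p = 0.722 with an estimated correlation), but its libraries differed. The list's mean log2 CPM was 6.29 and 4.81 in the 2 shallow BM24 libraries, and 2.13 and 4.33 in the other 2, which lay on either side of the parental range of 2.44 to 3.34. The mean of the latter pair, 3.23 ± 1.56, was within their spread of the parental 2.99. Act57B, Mhc and Acp26Aa were named here after their values were seen.

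In L3 testes CG13675 was at 66.5 ± 3.86 CPM in the parental stock and stood at log2 changes of −8.31 in BM1, −9.95 in BM5, −8.67 in BM6, −9.39 in BM46 and −9.26 in BM4. Pp1-Y1, a Y-linked phosphatase gene with a close copy that leaves its reads uncertain, had 0 parental counts and was at least 178-fold higher in BM6, 48.7 in BM46, 134 in BM4 and 221 in BM21. Also at 0 in the parental stock were lncRNA:CR44750 (at least 47.5-fold in BM1, 39.8 in BM5, 83.3 in BM6), lncRNA:CR43652 (93.1 in BM24, 47.9 in BM46, 86.0 in BM21) and CG8960 (73.1 in BM24, 175 in BM4), and lncRNA:CR43451 rose by 8.20 ± 0.41 in BM1. CG42714 had 0 counts in BM5 (at least 187-fold lower), and CG8249 (−4.41 ± 0.26) and CG43795 (−3.68) led the falls in BM21. Of 12071 genes, 2711 rose and 2540 fell in BM1, 2662 and 2639 in BM5, 2794 and 2622 in BM6, 2801 and 2382 in BM24, 2855 and 2635 in BM46, 2431 and 2115 in BM4, and 2313 and 1893 in BM21 (edgeR). The prevailing direction depended on scaling in BM4, with 2166 higher and 2326 lower by DESeq2 size factors, 2100 and 2326 in DESeq2 itself, and 3059 and 1762 by library size alone. By library size alone it also turned in BM1 (2485 and 2823) and BM5 (2468 and 2844), and in BM5 DESeq2 had 2622 and 2624. Totals averaged 5328 ± 124 in sterile and 4376 in fertile translocations (exact permutation test, two-sided, p = 0.0476, the smallest that 21 splits allow). As in adults, only the fertile lines share their stock maintenance with the parental stock, so fertility and stock are not separated here.

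By list, L3 fat body genes rose in BM1 (13 higher, 1 lower of 17), BM6 (10 higher, 1 lower) and BM46 (12 higher). Limma's adjusted p was 0.00517, 0.0427 and 0.0180, and 0.525, 0.808 and 0.706 with an estimated correlation. The list did not pass in BM5 (11 higher, 1 lower), BM24 (10 higher, 1 lower), BM4 (4 higher) and BM21 (3 higher, 1 lower). The Y-linked list went in opposite directions in BM6, where 9 of 12 rose (median 0.81, adjusted p = 1.86e-04, limma), and in fertile BM4, where 8 fell and 1 rose (median −0.51, mean 0.33, adjusted p = 0.0134). The gene kl-3 stood at 0.80 ± 0.16 in BM6 and −1.30 ± 0.19 in BM4. With an estimated correlation the adjusted p was 0.340 in BM6 and 0.323 in BM4. BM4 was also lower for sperm nuclear proteins (7 of 12), leucylaminopeptidases (4 of 8), differentiation genes (8 of 18), the testis-specific proteasome (8 lower, 1 higher of 14) and cup and comet genes (5 lower, 1 higher of 17), and higher for cyst and hub genes (12 of 24). Limma's adjusted p was 0.0115, 0.0115, 0.0131, 0.0233, 0.0233 and 0.0234 in that order. With an estimated correlation the adjusted p was 0.323 for each of these except cup and comet genes, at 0.444. Muscle and hemocyte markers stood higher in the same BM4 libraries, without a list call: 6 of 14 muscle genes rose and 1 fell (median 0.75, adjusted p = 0.139, limma), and 3 of 9 hemocyte genes rose and 1 fell (median 0.36, 0.0690). Their mean log2 CPM was 2.28 ± 0.07 for muscle against 1.81 ± 0.03 in the parental stock, and 3.37 ± 0.11 for hemocytes against 2.76 ± 0.05 (SD). Both were above the parental stock in the other 6 lines too, at 1.98 to 2.32 and 3.19 to 3.69. Cyst and hub genes also rose in BM1 (11 higher, 2 lower, adjusted p = 0.0418, limma) and BM46 (13 higher, 3 lower, 0.0180), with an adjusted p = 0.525 and 0.706 with an estimated correlation. Hemocyte genes rose in BM5 (6 of 9, adjusted p = 0.0428, limma) and BM46 (6 of 9, 0.0425), with an adjusted p = 0.153 and 0.324 with an estimated correlation. Ribosomal protein genes rose in BM24 (28 of 55, adjusted p = 0.00142, limma) and fell in BM6 (16 lower, 1 higher, 0.00956), with an adjusted p = 0.673 and 0.930 with an estimated correlation. kl-3 was named after its values were seen.

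Because the translocations exchange parts of the X and chromosome 2, the mean level of each arm was set against chromosome 3. The X did not differ between sterile and fertile lines in adults (0.0606 ± 0.0433 against 0.0391 ± 0.0239 log2 units, SD over 5 and 3 lines; exact permutation test, two-sided, p = 0.482) or in L3 (0.127 ± 0.0346 against 0.103 ± 0.0217; exact p = 0.321). Taken as the X count in percent of the chromosome 3 count, which weights abundant transcripts, it was higher in sterile lines by 3.59 points in adults and 2.16 points in L3 (exact p = 0.0179 each, the smallest of 56 splits). Y genes were higher by 0.26 in adults (exact p = 0.107) and 0.37 in L3 (exact p = 0.0714), and 2L, 2R and chromosome 4 had exact p-values of 0.214 to 0.964. The Y level was −1.43 in the shallow BM6 library and −1.24 and −0.93 in those of BM24, against −0.35 to 0.04 and −0.11 to −0.06 in the other libraries of these lines. Without the 3 shallow libraries the adult Y difference was 0.43 (exact p = 0.0714). That of chromosome 4 went from 0.08 (exact p = 0.214) to 0.10 (exact p = 0.0179, the smallest of 56 splits, not adjusted over the 5 arms), and the X, 2L and 2R had exact p-values of 0.679 to 0.821. Against the parental stock, 25 of 35 arm levels differed in L3 at an adjusted p of 0.04 (exact permutation, the smallest possible p of 0.0286), such as the Y in BM6 by 0.73 and BM46 by 0.41, chromosome 4 in BM1 by 0.36 and 2R in BM24 by −0.11. With medians over genes in place of means the count was 0. Mean chromosome 4 levels in L3 were above the parental −0.49 in every line, at −0.31 to −0.12. Mean 2R levels in L3 were below the parental 0.12 in every line except BM5, at 0.13. The same parental libraries enter all these comparisons, so such shared differences rest partly on them. In adults 0 of 35 passed (exact permutation, lowest adjusted p 0.0625). An arm level at the smallest possible p passes adjustment only when enough others share that p. The counts of 25 and 0 therefore depend on such ties and do not show that adult arms were unchanged. In adult BM46 the Y (by 0.59) and in adult BM4 2R (by −0.09) had all libraries beyond the parental ones (unadjusted exact p = 0.0286).

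Along the X, however, expression in the sterile lines BM1 and BM5 was uneven in 2 Mb windows, a view chosen after the values were seen. In BM1 genes on the low-coordinate side of 13128952 had a median log2 ratio to the parental stock of 0.20 in L3 and 0.25 in adults, and those on the other side −0.06 and −0.08. In BM5 the higher side was the opposite: 0.18 in L3 and 0.17 in adults at coordinates from 11899996 on, against −0.05 and −0.09 before it.

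**Figure D3:**
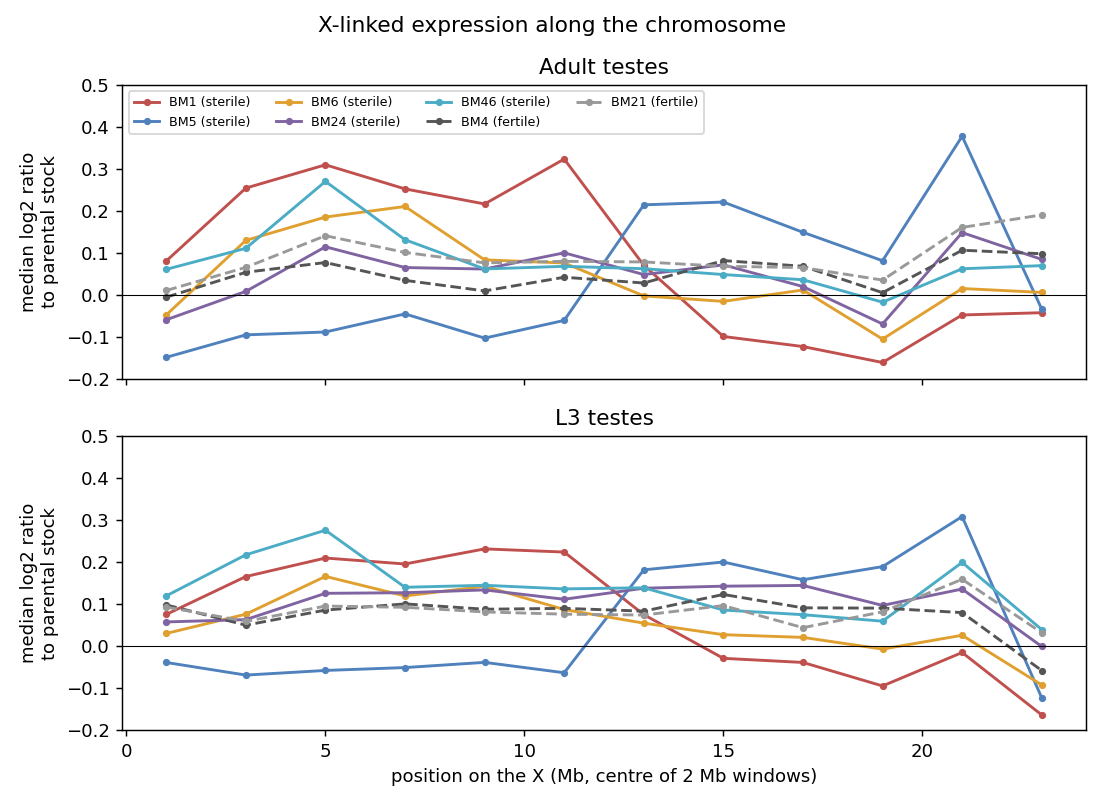
Median log2 ratio to the parental stock of genes in 2 Mb windows along the X, by window centre in Mb, for adult and L3 testes (solid lines sterile, dashed lines fertile; windows with at least 20 genes). BM1 lies at 0.32 in adults for the window from 10 Mb and −0.10 for the window from 14 Mb, and BM5 at −0.06 and 0.22.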

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

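None of the tests in this part was chosen after its result was seen. Across 50 sets of libraries or lines (total counts, genes detected and X levels), 3 held a library far from the others, where chance gives about 1 set in 20. In adult BM6, replicate 3 detected 4848 genes and the others 14483 to 14809, and it is also the library with 20387 counts. In L3 BM46, the X level relative to chromosome 3 was 0.145 in replicate 4 and 0.184 to 0.189 in the others. In L3 BM4, replicate 4 had a total count of 9644557 and the others 15722342 to 16785351.

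Other groupings of the same samples were tested for each count of differing genes. For sterile against fertile lines, 1 of 56 splits of the 8 lines, the real one, gave as many genes as observed: 375 in adults with at most 22 in another split, and 726 in L3 with at most 31. Chance assignment of lines to the classes can therefore be excluded at that level, which says nothing of stock and class, since these are the same split. For the interaction the observed count was 0 (edgeR, with 1509 at an unadjusted p under 0.05, and 190 in DESeq2), which any split reaches (56 of 56, the highest at 28), so these splits say nothing about chance there. For stage in the parental stock, 1 of 35 splits gave as many genes (8419 against at most 0).

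For the lines against the parental stock, 1 of 35 splits, the real one, gave as many genes in each of the 14 comparisons. The highest counts of other splits in adults were 525 for BM1, 117 for BM5, 2880 for BM6, 1695 for BM24, 41 for BM46, 160 for BM4 and 41 for BM21. In L3 they were 8 for BM1, 41 for BM5, 1506 for BM6, 13 for BM24, 572 for BM46, 527 for BM4 and 1149 for BM21. Random assignment of libraries was excluded in these comparisons at 1 in 35, which rests on the spread between pools.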

How the results depend on the processing

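The tests without shallow libraries or without libraries rich in accessory gland transcripts, the lists without a line and the median form of the arm levels were chosen after results were seen. Of 331 alternative values of the summary results, 278 stayed within 1.5 times or on the same side of the threshold, 33 were weaker and 20 stronger. That 0 were reversed says little, since only arm level differences could be labelled so and counts of calls could not. The prevailing direction of adult class calls did turn, from 53.6% higher to 36.3% when scaled by library size alone. Of 4845 values for named genes, 4241 were the same, 198 weaker, 403 stronger and 3 reversed. DESeq2 gave no adjusted p for 1 named gene. The cause was not tested in any case below unless it is stated. Adult class calls (375) became 1612 with DESeq2, 2542 with limma voom and the line as a random effect, 34 with the plate row, 191 without the parental stock, and 110 to 378 with each line left out. L3 class calls (726) became 1400, 1589, 238 and 404 to 851 in the same runs, apart from the parental stock, whose omission stayed within 1.5 times. The plate row fits rest on fewer lines, since a row without both classes adds nothing to the class difference. In adults this left out the parental stock and BM46, and in L3 BM24 and BM46. Treating the 32 libraries as replicates gave 6379 in adults and 6744 in L3, since libraries of a line then count as independent. The interaction (0) had 190 with DESeq2, 9 with DESeq2 size factors, 8 without a low-count filter, 8 without libraries rich in accessory gland transcripts, and 0 to 4 with each line left out (4 without BM21 or BM5). Adult line counts with DESeq2 were 4090 (BM1), 2072 (BM5), 2696 (BM6), 1887 (BM24), 2267 (BM46), 1154 (BM4) and 1182 (BM21). BM24 had 1882 in a fit of its own 8 libraries, BM6 2807 without libraries rich in accessory gland transcripts, and BM4 3487 and BM21 3788 without the shallow libraries. That BM6 fit kept 2 libraries of the line, including the shallow one. Leaving out each replicate kept every line count within 1.5 times, for instance 2661 to 4025 in adult BM24 and 3573 to 4305 in L3 BM21. Lists called went from 6 in adults and 4 in L3 to 0 and 0 with an estimated correlation, to 3 and 2 with 32 libraries, and to 2 to 8 and 1 to 6 with each line left out. The X difference became 3.59 points (adult) and 2.16 points (L3) as a percent of the chromosome 3 count, which weights abundant genes, and the 25 L3 arm levels became 0 with medians over genes. That 0 can arise when too few arm levels share the smallest possible p to pass adjustment. Reversed were adult Lsp1alpha with voom (−0.90, adjusted p = 0.788), L3 tHMG1 without BM4 (−0.00094, adjusted p = 0.997, edgeR, with up to 0.26 when another line was left out) and adult Ste12DOR without the libraries rich in accessory gland transcripts (0.042, adjusted p = 0.969, edgeR); none was called. The share of higher genes in adult DESeq2 calls was 62.3% in BM1 (52.3% in edgeR), 65.7% in BM24 (52.5%) and 67.5% in BM21 (56.1%), and in adult class calls 65.3%, 64.4% and 68.3% without BM21, BM46 or BM5. The replicate numbers do not pair the samples: correlations of deviations at the same number ran from −0.199 to 0.189 with a median of 0.00525, and 0 of 15 comparisons had all above 0.1. With the replicate number as a block, counts were 6167 (adult class, 32 libraries), 6716 (L3 class, 32 libraries), 3135 (interaction, 64 libraries), 7902 (stage), 2105 to 6299 for adult lines and 4100 to 5437 for L3 lines, and the line and stage counts stayed within 1.5 times. Without the shallow libraries the adult chromosome 4 difference between the classes became 0.10 (exact p = 0.0179, not adjusted over the 5 arms). Those libraries, of 20387, 43347 and 233047 counts, detected 4848, 5759 and 9417 genes; how far depth limits each line was not compared.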

Other observations

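The test of a shared trend and that of an extra copy in the X pattern, and the question of a response to sterility, were set after their results were seen, as were the step search and the comparison by expression level. The X steps differed with expression level, and of 4 levels the widest gap was among abundant transcripts in adults and among scarce ones in L3. In genes above a mean log2 CPM of 6, BM1 had a median of 0.51 on the higher side and −0.14 on the other in adults (0.29 and −0.04 in L3), and BM5 0.70 and −0.02 (0.31 and −0.02 in L3). In L3 genes under a mean log2 CPM of 2, BM1 had 0.40 and −0.10, and BM5 0.35 and −0.01. BM1 also had a smaller step on 2R at 21987068 (statistic 10.4 in L3, 6.04 at that position in adults), with genes beyond it at a median of −0.17 at both stages. Smaller L3 statistics above the chromosome 3 maximum of 4.31 were found on the X in BM6 (6.59), BM46 (4.85) and BM24 (4.41), and on 2R in fertile BM4 (5.66), BM46 (5.02) and BM24 (4.76). At the same positions in adults they were 5.22, 4.22 and 2.98 on the X, and 4.12, 2.70 and 3.37 on 2R. Of these only BM6 passed the adult chromosome 3 maximum of 5.20. The 2R positions in BM4 (6020311) and BM24 (5413744) lay near the best L3 cuts on 2R in BM5 (5937400, statistic 2.44) and BM21 (5967397, statistic 4.21). The breakpoints are not in the labels, so these positions were not compared with them.

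The steps of X expression in BM1 and BM5, at 13128952 and 11899996 with statistics of 15.3 and 14.3 in L3 (13.4 and 16.0 at the same positions in adults), stood above the highest value on chromosome 3, which was 4.31 in L3 and 5.20 in adults over 14 arms. A trend along the X common to all lines is argued against, since the fertile translocations reached at most 3.13 in L3 and 4.30 in adults (BM21), below the chromosome 3 maximum of each stage, and the steps of BM1 and BM5 run in opposite directions. A single deviating library is excluded, because 16 of 16 libraries of these lines showed the step in the same direction. A full extra copy of the higher segment would put its genes about 1 log2 unit up if RNA followed copy number. That is argued against, since the highest upper bound of the 95% bootstrap intervals of the median over all its genes was 0.29. No interval was taken for genes above a mean log2 CPM of 6 alone, which had a median of 0.70 in adult BM5. An extra copy with a weaker effect on RNA was not tested. A regional effect of the exchanged X segment, or inherited sequence differences between X chromosomes, may account for the steps, and nothing here separates these.

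Few X genes were among the class calls, and the classes differ in stock as well as in fertility. The scarcity is not peculiar to that contrast: against the parental stock the odds ratio of X calls was 0.404 in adults and 0.485 in L3 for fertile BM4, 0.646 and 0.626 for fertile BM21, both kept like that stock, 0.875 and 0.858 for sterile BM1, 0.771 and 0.816 for BM5, 0.906 and 0.802 for BM6, 0.842 and 0.601 for BM24, and 1.05 and 1.00 for BM46. Lower precision of X genes is argued against, since their median standard error was at most 1.01 times that of autosomal genes of like expression. Before adjustment the scarcity was milder. At an unadjusted p under 0.05 (edgeR) stood 15.8% of X and 23.5% of autosomal genes in adults, and 13.8% and 23.1% in L3. Median absolute log2 changes were 0.20 and 0.23 in adults, and 0.15 and 0.17 in L3. Inherited autosomal differences between stocks predict that called genes lie next to each other. In adults 21 neighbouring pairs stood against 12.3 in shuffled calls (p = 0.00799, permutation, one-sided). In L3 it was 76 against 44.8 (p = 0.000999, permutation, one-sided, the smallest that 1000 shuffles give). Both counts are what such differences predict, although genes that work together may also be neighbours. Overlapping genes, whose counts are uncertain here, were not set aside, so shared reads may add such pairs. The 195 genes called at both stages fit a difference between stocks as well as a response to sterility, and these cannot be told apart because every sterile line was kept over FM7i and every fertile one with C(1)M4.

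Fat body genes were higher in L3 pools of sterile lines, although fat body had been digested away. No line alone carries this, as the highest adjusted p with a sterile line left out was 3.99e-06 (limma, preset correlation), although with an estimated correlation the list did not pass with all lines in (adjusted p = 0.284). Fat body left on some testes may contribute: within lines, deviations of fat body genes correlated across the 32 libraries with a median of 0.208, against a median of −0.00136 and at most 0.154 in 1000 random lists matched on expression, but this lies between the values set in advance for and against it (0.3 and 0.1), so left-over tissue and a difference between stocks or classes cannot be told apart. A biological difference in the sterile lines stays open and untested.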
